A study of Xenopus tropicalis with 8 samples.

How the data were processed

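The series measured small RNA in 5 libraries and polyadenylated mRNA in 3 libraries of untreated wild-type embryos of the frog Xenopus tropicalis. Small RNA came from whole embryos at stage 8, stage 10 and stage 18 and from the animal and the vegetal pole at stage 10. The mRNA libraries came from whole embryos at the same 3 stages. Each group held 1 library, so no difference between groups had a replicate check and no p-value was computed. Groups were taken from the sample titles.

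Per the labels' protocols, RNA of 18 to 30 nt was selected on a gel, ligated to adapters with T4 RNA ligase, amplified by PCR and sequenced from a single end. The same protocols state that polyadenylated RNA was fragmented and copied into double-stranded cDNA for the mRNA libraries, and do not say whether strand was kept. BWA, Bowtie, TopHat and bedtools are named in the submitters' processing notes without a version or a role. The genome build is not given in the sources used here; positions are those of the deposited files, counted from 1, on numbered scaffolds. No annotation on that build was used here, so loci carry coordinates in place of gene names, and the gene and microRNA lists fixed beforehand were not applied.

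The deposited small RNA files list each aligned sequence with its read count and its number of places in the genome, and a sequence appears once per place. Read counts in these deposited files are whole numbers and not normalized. Each read was divided by its number of places at loci, in shares of exons and introns and in finding peaks. Reads and RPM of peaks are full, undivided counts of the sequences that start there, wherever else these align. Opposite-strand overlaps counted every place of a sequence in full. The deposited mRNA files hold 1 alignment of a 60 nt read per line, with a score by the authors that was 255 for most reads; 255 was read as alignment to 1 place, which no header states. Between 82.0% and 89.6% of mRNA reads had that score and were counted.

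Without gene models, transcription units were built from the pooled mRNA reads. Covered stretches within 200 nt of each other were joined, and stretches connected by at least 2 spliced reads with at least 8 nt on the shorter side became a single unit, with introns of at most 100000 nt. The 2 reads could be copies of 1 alignment. Unspliced stretches needed 100 reads. This gave 31260 units, of which 26241 were spliced, and the units took 90.2% to 92.1% of the counted reads. Exon and intron below mean parts of these units. The median spliced unit held 1 junction, so many units are fragments of genes. Strand was ignored for mRNA.

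Small RNA loci were stretches of 25-30 nt reads with neighbours within 200 nt, at least 50 RPM (reads scaled to a total of 1000000) and at least 20 distinct 5′ ends, called in each library and, for counting, on the pooled libraries (1493 loci). Levels at loci were RPM of 25-30 nt reads, compared where 1 of the libraries had at least 500 reads. Peaks of 20-24 nt reads stood in for microRNAs: positions holding at least 80% of the 20-24 nt reads within 10 nt on their strand, with at least 200 reads in 1 library, and copies sharing their most abundant sequence counted once. Opposite-strand overlaps were counted between distinct 5′ ends, and the count at 10 nt was set against the mean and SD of the counts at the other overlaps from 1 to 20 nt as a Z-score.

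A locus was called exonic or intronic where exons or introns covered at least 50% of it. Levels of 20-24 nt peaks were RPM of 20-24 nt reads. The mRNA ratios were log2 ratios of CPM (counts scaled to the same total) with a prior of 1 read, for units with at least 50 reads in 1 of the libraries compared, and units at least 4-fold apart were counted. Shares have exact Clopper-Pearson 95% intervals and ratios have exact intervals from the binomial split of the counts. For single mRNA units the interval was computed on distinct alignments, since reads lay in stacks of 6.39 to 9.61 reads per distinct alignment. PCR reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only. For peaks, a fold against a library with 0 reads was computed against 3 reads and bounds counting error in reads only. For mRNA units with 0 reads at a stage, the limit given is that of the interval on distinct alignments. Units with a small RNA locus in an intron were compared with 10000 random lists of units matched on length, both limited to spliced units with at least 50 mRNA reads at 1 of the stages.

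The rule for named loci was set before the data were examined. It took, in place of 10 genes, the 3 units with the largest ratio each way among those with at least 200 reads in the higher library; the 3 loci with most reads in each library and the 3 with most reads in introns; the 3 loci with the largest ratio each way between the poles; and for peaks the 3 with most reads and the 3 with the largest ratio each way.

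Main counts were repeated under other scalings (trimmed mean of M-values and median of ratios), read minimums, priors, merge distances and ways of counting reads that align to several places. The functions were tested on simulated data. With Poisson counts for the real units, 100% of 200 units changed 8-fold were recovered between stages 10 and 8 among 13761 units, with 0 false calls. With molecules amplified at random into stacks of the observed mean height, 94.0% of 200 were recovered among 14943 units with 815 false calls, and for stages 18 and 10 the figures were 92.0% among 15619 units with 1319 false calls. For the poles, 100% of 200 loci changed 3-fold were recovered at a threshold of 2-fold among 714 loci. Those counts were Poisson, with no amplification, so they do not test its effect on small RNA. Changes were planted only in units and loci with many expected reads, so the recoveries do not hold for those with few. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyarrow 21.0.0 and matplotlib 3.10.9.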

Results

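Small RNA and mRNA were profiled in embryos of Xenopus tropicalis at the blastula (stage 8), the early gastrula (stage 10) and the neurula (stage 18), and small RNA was also profiled in the animal and the vegetal pole of the stage 10 embryo. The animal pole gives rise mainly to ectoderm and the vegetal pole mainly to endoderm. Each group was 1 library, so differences have no replicate check and compare these libraries only. The small RNA files held 6387223 reads at stage 8, 7253295 at stage 10, 5543204 at stage 18, 5350423 in the animal pole and 4756164 in the vegetal pole. These reads fell on 395582, 218132, 325424, 312348 and 424887 distinct sequences. The mRNA files held 5952000, 5735573 and 6771777 reads at stages 8, 10 and 18. Bases 2 to 17 of 9 well-known microRNAs, among them let-7a and the early embryonic miR-427, occurred in 0 reads of every library. The sources used here do not say whether annotated microRNAs were left out of the files. If they were, these totals are not library depths and the 0 sets no limit on their level. RPM and shares of read lengths therefore refer only to the reads in the files.

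The first comparison asked how the lengths of small RNAs differed between stages and poles. Reads of 25-30 nt, the length of RNAs bound by PIWI proteins (piRNAs), were the main class in the files of all 5 libraries. The most frequent length was 28 nt in each. If microRNAs were left out of the files, the shares of both length classes in the embryo would differ from those given here. They made up 74.2% of reads at stage 8 (95% interval 74.2 to 74.3), 83.1% at stage 10 (83.1 to 83.1) and 74.0% at stage 18 (74.0 to 74.1). The animal pole had 71.7% and the vegetal pole 75.4%, so both poles lay below the whole embryo of the same stage. Reads of 21-23 nt showed the opposite order, with 16.3% at stage 8, 9.76% at stage 10, 16.4% at stage 18, 17.8% in the animal pole and 15.3% in the vegetal pole. Counted as distinct aligned positions in place of reads, the share of the 25-30 nt class at stage 10 minus that at stage 8 was −0.817 percentage points, against 8.84 by reads. The difference between the poles, 3.69 points, came to 0.453 points with the class set to 24-29 nt.

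**Figure D1:**
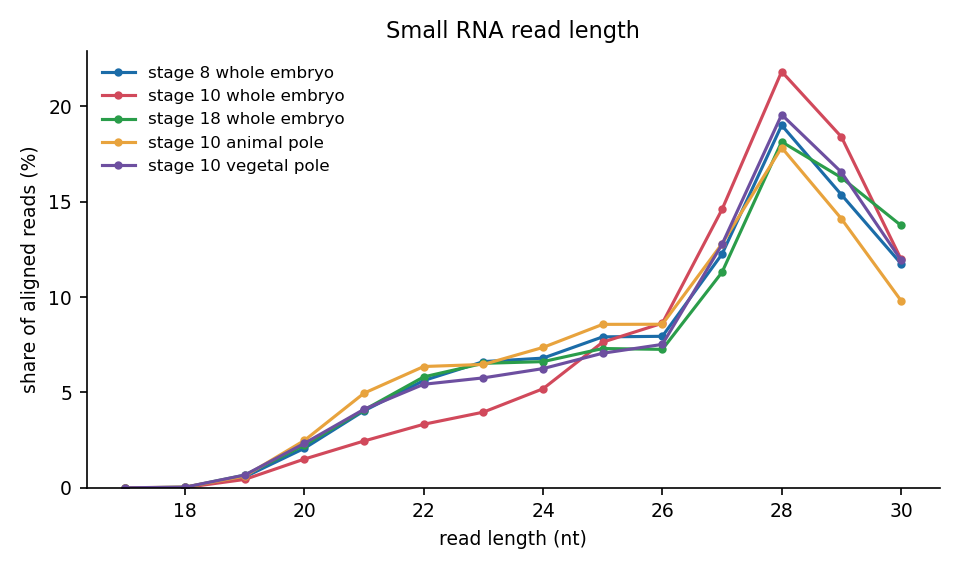
Share of aligned small RNA reads (%) at each read length (nt) in the 5 libraries, 1 line per library. All lines peak at 28 nt, and the stage 10 whole-embryo line is the lowest at 21-23 nt (9.76% of its reads in all).

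The second comparison looked for pairs of 25-30 nt reads on opposite strands whose 5′ ends overlap by 10 nt, the mark of RNAs made by reciprocal PIWI cleavage. In every library the 10 nt overlap had more pairs than any other overlap from 1 to 20 nt. Its Z-score was 6.65 at stage 8, 5.45 at stage 10, 6.90 at stage 18, 7.21 in the animal pole and 8.65 in the vegetal pole. It held 66092 pairs at stage 8, 15317 at stage 10, 57426 at stage 18, 59513 in the animal and 86713 in the vegetal pole, or 3.52, 2.75, 4.08, 3.84 and 3.48 times the mean of the other overlaps. The whole-embryo library of stage 10 also had the fewest distinct 5′ ends, 1369116 on the plus strand against 1989596 and 2606041 in the poles. Of 25-30 nt reads, 50.6% to 55.2% began with U, and A stood at base 10 in 50.7% to 54.0% of reads that did not begin with U, against 41.8% to 44.9% of those that did. In 21-23 nt reads the Z-score was 2.52 at stage 8, −0.227 at stage 10, 1.40 at stage 18, 2.70 in the animal pole and 9.02 in the vegetal pole. Reads aligned to 1 place gave 18 to 68 pairs at 10 nt per library, against 15317 to 86713 with all reads.

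**Figure D2:**
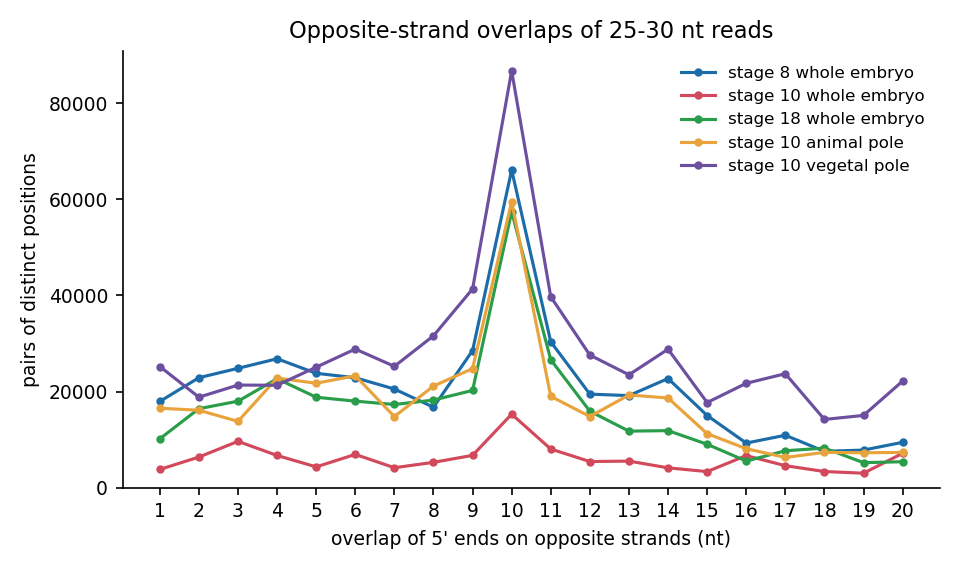
Pairs of distinct 5′ ends of 25-30 nt reads on opposite strands by overlap (nt) in the 5 libraries, 1 line per library. Each line is highest at 10 nt, from 15317 pairs at stage 10 to 86713 in the vegetal pole.

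The third comparison asked whether the same places gave rise to small RNAs at each stage. The strongest locus in all 5 libraries lay on scaffold 1101 from 107524 to 135942, with 46448 RPM at stage 8, 29823 at stage 10, 44005 at stage 18, 41450 in the animal pole and 42820 in the vegetal pole. The 9 loci of that scaffold between 77370 and 181766 took 8.65% of 25-30 nt reads at stage 8, 6.31% at stage 10, 8.27% at stage 18, 8.08% in the animal and 8.25% in the vegetal pole. All 9 were read mainly from the plus strand, and 0.00288% of their reads over the 5 libraries lay on the minus strand. A locus on scaffold 592 (574371 to 596850) had 22360, 17732, 22459, 24239 and 22994 RPM in the same order of libraries. A locus on scaffold 1071 (2573 to 23894) had 21398, 20668, 18798, 16566 and 24039, and a further locus of scaffold 1101 (167324 to 181766) had 17039, 18903, 16632, 18013 and 17108. Reads at 1 place made up 20.8% of the strongest locus, 12.1% on scaffold 592, 6.91% on scaffold 1071 and 24.4% at the last. In all, 1348 loci were called at stage 8, 1353 at stage 10, 1220 at stage 18, 1378 in the animal pole and 1413 in the vegetal pole. Their median length ran from 1094 to 1366 nt, and 96.2% to 97.3% of them had at least 95% of reads on a single strand.

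Most loci were shared between libraries. Of the stage 8 loci, 83.7% overlapped a locus of stage 10 and 83.8% a locus of stage 18, and 947 (70.3%) overlapped a locus in each of the 4 other libraries; these held 92.0% of the reads in stage 8 loci. Of pooled loci with at least 500 reads in 1 of the libraries compared, none differed at least 4-fold between stages: 0 of 1184 between stages 8 and 10, 0 of 1161 between stages 10 and 18 and 0 of 891 between stages 8 and 18. With no minimum, 6 of 1493 were at least 4-fold lower at stage 10 than at stage 8 and 6 higher at stage 18 than at stage 10. At least 2-fold, a threshold chosen after the data were seen, 9 loci were higher and 16 lower at stage 10 than at stage 8, and 2 were higher and 15 lower at stage 18 than at stage 10. With reads aligned to 1 place only, 151 to 257 loci per library passed the minimums, and 59.6% of the stage 8 loci overlapped one of stage 10.

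**Figure D3:**
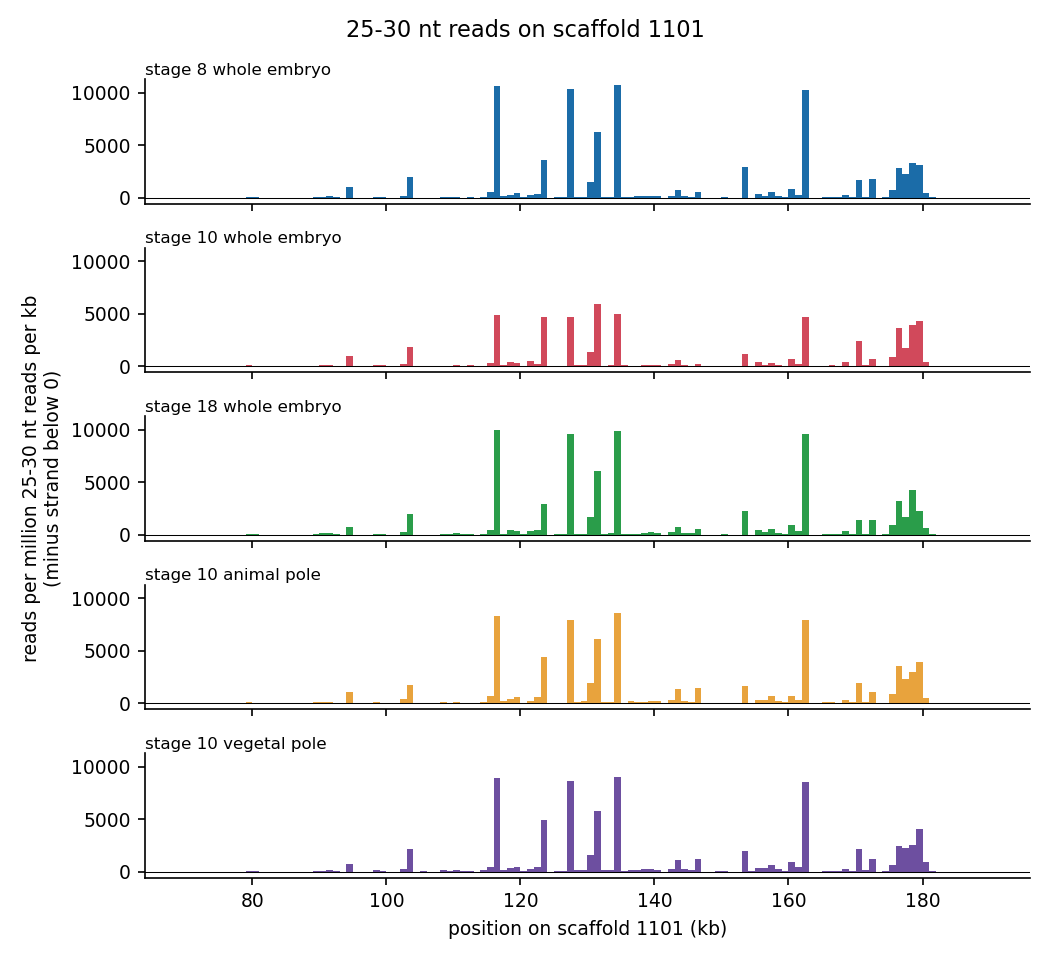
RPM of 25-30 nt reads in bins of 1 kb along scaffold 1101 (kb), 1 panel per library, with the plus strand above and the minus strand below 0. In all 5 panels the reads lie almost wholly on the plus strand, and the 9 loci hold 6.31% to 8.65% of 25-30 nt reads.

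Loci lay mostly outside the transcription units, whose exons covered 21.2 Mb and introns 129 Mb. The share expected from these areas was not computed, so a preference for or against units was not measured. Of the stage 8 loci, 50 (3.71%) lay in introns, 2 in exons and 1296 outside units, and in the other libraries 3.92% to 4.18% lay in introns. The intronic locus with most reads in each whole-embryo library lay on scaffold 845 (338936 to 340059), near a further intronic locus (340322 to 341175). Both overlapped, and reached past, a unit at 339275 to 341164 that had 3 mRNA reads at stage 8 and 0 at the later stages. Those reads were 1 distinct alignment, so that unit and its intron rest on a single stack. The first locus had 1443 RPM at stage 8, 1195 at stage 10 and 1205 at stage 18. On scaffold 6387 an intronic locus (737 to 1352) had 1138, 779 and 922 RPM at the 3 stages, and it had the most reads of all intronic loci in the animal pole (8015). On scaffold 737 a locus at 316083 to 317124 had 542, 712 and 485, and the unit around it (235563 to 350415) had 0 mRNA reads at stages 8 and 10 and 380 at stage 18. Nearly all reads of these 4 loci also aligned elsewhere: those at 1 place made up 0.352% and 2.48% on scaffold 845, where both loci had the same most abundant sequence, 0.0272% on scaffold 6387 and 0.0397% on scaffold 737. Their levels are therefore shares of repeated sequences. Of all 25-30 nt reads, 2.40% to 2.81% fell in introns and 96.9% to 97.3% outside units.

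How the mRNA level of units with an intronic locus compared with that of units of similar length depended on which units were kept. With at least 50 mRNA reads at 1 of the stages, which kept 28 of 48 such units at stage 8, the median log2 CPM at stage 8 was 5.27, against 5.04 for random lists (percentile 71.2). At stage 10 it was 5.33 over 29 of 50 units against 4.94 (percentile 83.0), and at stage 18 it was 5.02 over 27 of 47 units against 4.26 (percentile 94.4). Without that minimum, an alternative chosen after the data were seen, the medians were 3.32 against 3.92 (percentile 8.28), 2.64 against 3.79 (percentile 1.95) and 2.80 against 2.97 (percentile 37.8). Among units with at least 50 reads, the median log2 ratio of stage 10 to stage 8 was 0.00 against −0.05 (percentile 75.1). The median log2 ratio of stage 18 to stage 10 was −0.98 against −1.10 (percentile 63.1), and with lists matched on mean expression the random median was −0.50 (percentile 8.91). With loci of at least 200 RPM at stage 8, only 3 of 5 units had at least 50 mRNA reads, with a stage 8 median of 2.96 against 5.06 (percentile 2.24). Units are not independent replicates, and the percentiles describe these libraries.

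Small RNA loci of the animal and vegetal pole were compared next. Of 839 loci, 23 were at least 2-fold higher in the animal pole and 5 in the vegetal pole, and 811 lay within 2-fold. The largest animal-pole ratios were at scaffold 200 from 1482571 to 1483565 (3.56-fold, interval 3.07 to 4.14), scaffold 36 from 2601545 to 2602297 (3.38-fold, 2.84 to 4.06) and scaffold 699 from 57888 to 59685 (3.05-fold, 2.83 to 3.28). The largest vegetal-pole ratios were at scaffold 18215 from 2561 to 3327, an exonic locus (4.36-fold, 3.79 to 5.03), scaffold 358 from 1040860 to 1042707 (2.53-fold, 2.37 to 2.71) and scaffold 4056 from 5922 to 9485 (2.14-fold, 1.94 to 2.37). At scaffold 358 the whole embryo of stage 10 had 1123 RPM, above both the animal (317) and the vegetal pole (805). Reads at 1 place made up 0.226% at scaffold 200 and 9.71% at scaffold 4056, and at least 99.6% at the other 4. The locus on scaffold 6387 in an intron was 1.93-fold higher in the animal pole. The median log2 ratio of all loci was 0.19 and became 0.06 with median-of-ratios scaling, which counted 10 loci higher in the animal and 12 in the vegetal pole. Scaled to all reads the counts were 13 and 7.

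**Figure D4:**
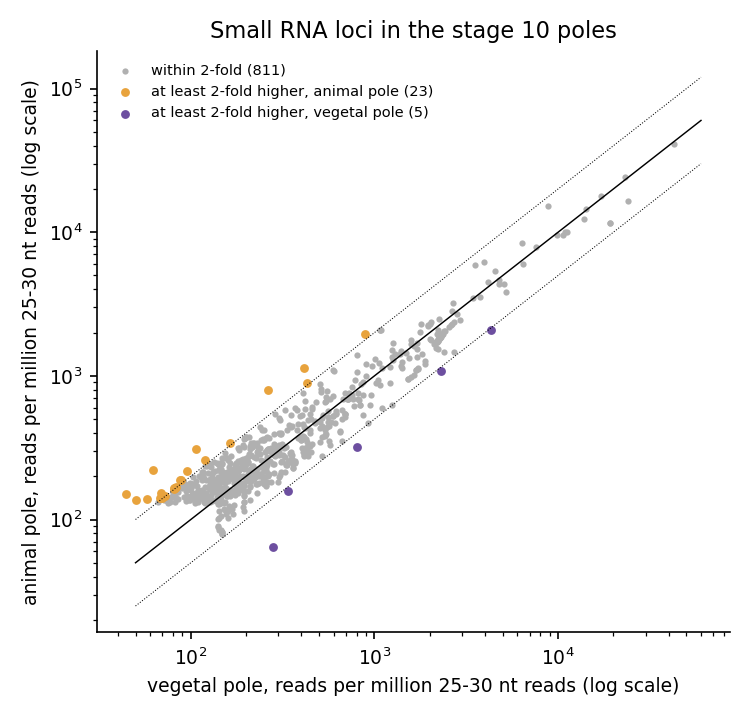
RPM of 25-30 nt reads of 839 small RNA loci in the stage 10 animal pole against the vegetal pole, both on log scales, with the solid line at equal levels and dotted lines at 2-fold. Loci at least 2-fold higher are coloured, 23 for the animal and 5 for the vegetal pole.

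Peaks of 20-24 nt reads with a dominant 5′ end stood in for microRNAs, and 502 reached 200 reads in 1 library. Of these, 248 had at least 80% of their reads at 20-24 nt. Counts of peaks below are therefore not counts of microRNAs. The peak with most reads, on scaffold 592 from 552666 to 552688 (AGCAGAGGGCTGAAAGGAAATGA, 65.6% of its reads at 20-24 nt), had 91797 reads at stage 8, 33266 at stage 10 and 63335 at stage 18. Next came a peak on scaffold 592 (531284 to 531307) with 25775 reads at stage 8 but 7.15% of its reads at 20-24 nt, and a repeated sequence on scaffold 29 (1741759 to 1741782) with 23693. In order, the most abundant sequences of the top peak and of these aligned to 4, 8 and 54 places. A peak at a single place, chosen after the values were seen, on scaffold 582 (107060 to 107081, AGAGCAGAAATCGTGGCAGTAG) had 99.8% of its reads at 20-24 nt and 17235, 16199 and 22778 reads. Among whole-embryo libraries, some peaks had nearly all their reads at the neurula. On scaffold 377 (230685 to 230705, TGGACATGATGCAGACTGACT) reads numbered 4 at stage 8, 60 at stage 10 and 3266 at stage 18, 936-fold higher at stage 18 than at stage 8 (365 to 3438), with 263 in the animal and 187 in the vegetal pole. On scaffold 715 (165058 to 165078) there were 0, 0 and 337 reads, at least 95.7-fold more at stage 18 than at stage 10 against a floor of 3 reads (exact lower limit 77.4), and on scaffold 1310 (81386 to 81405) there were 0, 5 and 714, with 0 and 67 in the animal and 0 and 44 in the vegetal pole. A peak on scaffold 166 (1930177 to 1930198) had 225 and 251 reads at stages 8 and 10 and 0 at stage 18, at least 98.2-fold lower than at stage 10 against the same floor (exact lower limit 79.3), with 46 in the animal and 50 in the vegetal pole. The other peaks with the largest ratios at stage 18 were on scaffold 39 (3202015 to 3202038, with 0, 3 and 384 reads), scaffold 88 (2092006 to 2092028, with 873, 1330 and 201) and scaffold 739 (291435 to 291457, with 207, 108 and 65). Their most abundant sequences aligned to 2, 4 and 1 places.

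Of 419 peaks, 20 were at least 2-fold higher and 9 lower at stage 18 than at stage 8. Between stages 10 and 8, 29 of 409 were higher and 48 lower (37.7% higher), against 3.47% higher when scaled to all reads and 74.1% with median-of-ratios scaling. Between stages 18 and 10, 59 of 398 were higher and 25 lower (70.2% higher), against 95.3% and 44.9% under these scalings. The median log2 ratio of stage 10 to stage 8 was −0.23, −0.84 and −0.03 under the 3 scalings and that of stage 18 to stage 10 was 0.26, 0.88 and 0.04. The medians thus kept their sign, near 0 under median-of-ratios scaling, which centres the peaks by design, while the balance of peaks past 2-fold turned under it. Both comparisons used the same stage 10 whole-embryo library, so their opposite medians are not independent results. Among peaks with at least 80% of reads at 20-24 nt, 10 were higher and 32 lower at stage 10 than at stage 8 (median −0.39), and 45 were higher and 8 lower at stage 18 than at stage 10 (median 0.39). On scaffold 10 a repeated sequence (4005710 to 4005730) was 62.6-fold higher at stage 10 than at stage 8 (34.7 to 126), with 512 against 11 reads. Repeated sequences on scaffold 75 (200438 to 200458) and scaffold 23 (3983878 to 3983899) were 43.3-fold (23.9 to 87.6) and 39.3-fold higher (22.2 to 76.7). They had 354 against 11 and 350 against 12 reads, and the last had 0 reads at stage 18. In order, these 3 rises had 2815, 853 and 353 reads in the animal and 899, 411 and 89 in the vegetal pole. Both poles thus also lay above stage 8, which was itself 1 library. The most abundant sequences of these rises aligned to 81, 35 and 84 places. The lowest ratios of stage 10 to stage 8 were on scaffold 780 (220183 to 220204, 29 against 203 reads, log2 ratio −2.35), scaffold 41 (2159229 to 2159248, 50 against 313, −2.20) and scaffold 778 (12547 to 12568, 79 against 435, −2.02). Reads on these 3 numbered 109, 377 and 367 in the animal and 124, 370 and 299 in the vegetal pole, and their most abundant sequences aligned to 1, 70 and 12 places.

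Between the poles 46 of 422 peaks were at least 2-fold higher in the animal and 23 in the vegetal pole (66.7% higher), and 83.3% were higher when scaled to all reads, which put the median log2 ratio at 0.32 in place of 0.11. Among peaks with at least 80% of reads at 20-24 nt the counts were 17 and 12 and the median was −0.05. A peak on scaffold 166 (1919153 to 1919174) had 3421 reads in the animal and 566 in the vegetal pole, 4.65-fold apart (4.25 to 5.09), but the whole embryo of stage 10 had 123 RPM there, below both the animal (2313) and the vegetal pole (498). On scaffold 612 (96258 to 96277) the animal pole was 5.78-fold higher (3.96 to 8.70), with 158 and 27.3 RPM in the poles and 1.68 in the whole embryo, and on scaffold 95 (472259 to 472280) 5.05-fold (4.14 to 6.22). Of the reads of these peaks 98.1%, 99.1% and 84.8% were of 20-24 nt, and their most abundant sequences aligned to 16, 5 and 6 places. The vegetal pole was 6.60-fold higher on scaffold 626 (120490 to 120512), 2.75-fold on scaffold 592 (538721 to 538741) and 2.66-fold on scaffold 5 (5240491 to 5240512, 2.61 to 2.72), but only 53.3%, 64.2% and 59.1% of the reads of these were of 20-24 nt. The peak on scaffold 5 had 24053 reads in the vegetal and 11743 in the animal pole. The most abundant sequences of the vegetal-pole peaks aligned to 13, 2 and 3 places. The coordinates given for the peaks of both poles are therefore 1 of several places.

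The last comparison concerned mRNA between stages. A unit on scaffold 136 (640918 to 647537, 23 junctions) had 0 reads at stages 8 and 10 and 28285 at stage 18. On distinct alignments the lower limit of its log2 ratio was 8.96 against stage 10 and 8.84 against stage 8. A unit on scaffold 440 (247482 to 258418) had 22647 reads at stage 18 and a unit on scaffold 68 (1795115 to 1803851) had 21844, each with 0 at the earlier stages. The unit with most reads at stage 18, on scaffold 167 (399413 to 405656), had 126 reads at stage 8, 1396 at stage 10 and 90178 at stage 18. In the other direction, a unit on scaffold 120 (1910114 to 1958919) had 4658 and 3465 reads at stages 8 and 10 and 0 at stage 18, and its log2 ratio of stage 18 to stage 10 on distinct alignments was at most −6.30. Its neighbour on the same scaffold (1962776 to 1970800) had 1296, 967 and 0 reads, and a unit on scaffold 87 (85885 to 89971) had 2226, 1440 and 0.

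At stage 18, 2579 of 16544 units were at least 4-fold higher and 3337 lower than at stage 10. The higher units were 43.6% of both, and 60.2% with trimmed-mean scaling and 62.1% with median-of-ratios scaling, which moved the median log2 ratio of all units from −0.54 to 0.05 and 0.12. Against stage 8 the counts were 2765 higher and 4078 lower of 17154 (40.4% higher, 58.6% and 60.5% under those scalings), and the median log2 ratio was −0.74 before and −0.03 and 0.04 after. On distinct alignments in the same units 2335 were higher and 2105 lower than at stage 10 (52.6% higher), and 2560 and 2558 against stage 8. With units chosen by a minimum of 10 distinct alignments, 2131 were higher and 2241 lower than at stage 10 (48.7% higher), and 2354 and 2590 against stage 8 (47.6%). Which direction prevailed therefore depended on the scaling, and counts on distinct alignments were near balance. Distinct alignments level off in units with many reads on few positions, so this balance does not decide the direction. A unit on scaffold 6267 (3449 to 4109) had a log2 ratio of stage 18 to stage 8 of 2.08 by reads and 0.67 on distinct alignments. The 10 units with most reads took 9.92% of the reads in units at stage 18, against 5.12% at stage 8 and 4.95% at stage 10.

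Stages 8 and 10 were far closer. Across 18082 units, which are not independent replicates, Pearson's correlation of log2 levels was 0.91 for stages 8 and 10, 0.25 for stages 10 and 18 and 0.16 for stages 8 and 18. The units with the largest ratios at stage 10 were on scaffold 232 (1364217 to 1367883, 0 reads at stage 8 and 284 at stage 10), scaffold 7 (2694499 to 2696602, 0 and 224) and scaffold 511 (363142 to 378280, 6 and 474). On distinct alignments the lower limits of the log2 ratio were 3.91 and 3.36 for the first pair, and the last had 4.84 (3.49 to 8.45), against 6.04 by reads. Lower at stage 10 were units on scaffold 308 (776219 to 779026, 515 and 44 reads, log2 ratio −3.57), scaffold 1176 (85995 to 87253, 223 and 37, −2.61) and scaffold 296 (1507441 to 1509825, 271 and 49, −2.49). On distinct alignments these ratios were −2.27 (−3.40 to −1.46), −2.80 (−4.52 to −1.76) and −1.80 (−2.90 to −0.96). In total 217 of 14778 units were at least 4-fold higher and 219 lower, and on distinct alignments in the same units the counts were 150 and 54. With units chosen by a minimum of 10 distinct alignments they were 165 and 48 of 15155, while the units meant below are those past 4-fold by reads. Of these units, 191 of the 217 higher and 139 of the 219 lower ones had an interval on distinct alignments that left out no difference. The intervals cover counting error only, in units picked by their ratio. Simulated reads in stacks of the observed mean height gave 815 units past 4-fold among those left unchanged, more than the 436 seen. A simulation with more such units than the data cannot tell how many of the 436 arose from stacks. For stages 18 and 10 the simulation gave 1319, against 5916 seen.

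**Figure D5:**
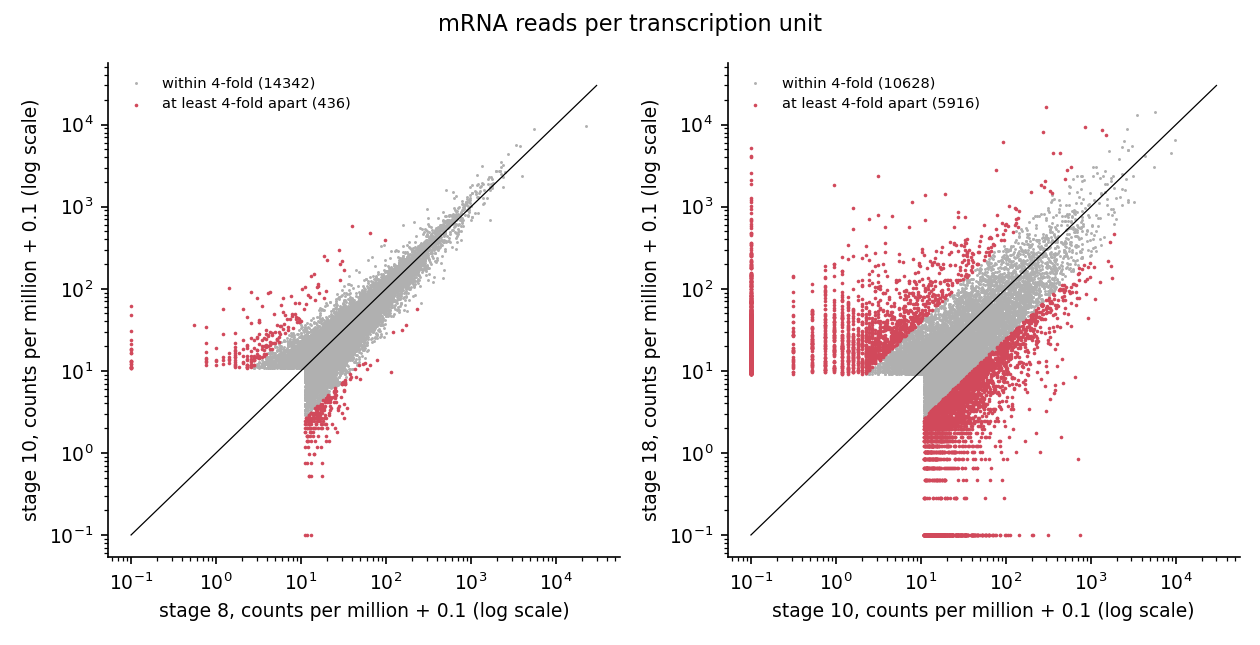
mRNA CPM plus 0.1 per transcription unit, stage 10 against stage 8 and stage 18 against stage 10, on log scales with the line at equal levels. Units at least 4-fold apart, 436 in the first panel and 5916 in the second, are coloured.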

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

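The 24 nt reads were tested only after the length classes had been seen. They lie outside both classes compared above and made up 7.36% of animal pole reads. In the animal pole library they had more opposite-strand pairs at an overlap of 10 nt (6020) than at any other overlap from 1 to 20 nt, with a Z-score of 6.37. In the other 4 libraries 10 nt was not the highest overlap of 24 nt reads, with Z-scores of 2.54 at stage 8, −0.230 at stage 10, 1.66 at stage 18 and 1.91 in the vegetal pole. Their pairs at 10 nt numbered 9887, 480, 4144 and 9613, or 3.81, 0.558, 3.19 and 2.88 times the mean of the other overlaps, against 5.49 times in the animal pole. An excess at 10 nt was thus not confined to that library. The difference between the libraries was not tested. With 1 library per group, no library was set against others of its own group.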

How the results depend on the processing

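The alternatives on loci with reads at 1 place or at their full count at every place, on distinct mRNA alignments and their intervals, on host units without a minimum of mRNA reads, on reads of any score, on shares in introns, on 24 nt reads, on peaks mostly of 20-24 nt reads and on 2-fold differences between stages were chosen after seeing the data; the others were fixed before the data were examined. Of 216 alternative values, 104 stayed within the tolerance set (1.5 times for counts, counting intervals for shares, 1 for Z-scores, the spread of random lists for medians), 110 moved and 2 turned direction. Only differences of shares and Z-scores could be classed as turned. Higher and lower counts were scored apart, so a change in which of them prevailed is counted under the other classes. Such changes, given above for mRNA units, peaks and loci of the poles, are not among the 2. A change of sign of the host mRNA medians is also counted under the other classes. These medians lay inside the 95% range of random lists for loci of at least 50 RPM and units of at least 50 mRNA reads. Where a value moved, the cause was not tested. No paired analysis was possible because each group held 1 library. Alternatives for reads by annotated class and for gene lists were not run, since no annotation on the files' build was used here, and neither was the one for loci antisense to the gene. With loci of at least 200 RPM, 3 of the 5 units with an intronic locus at stage 8 had at least 50 mRNA reads, and their median log2 mRNA level minus that of random units was −2.10 in place of 0.23. With no minimum of mRNA reads it was −0.60 at stage 8, −1.15 at stage 10 and −0.18 at stage 18, in place of 0.23, 0.39 and 0.76. The median log2 ratio of stage 18 to stage 10 minus that of random units was −0.48 with lists matched on expression, in place of 0.12. Only 2 of 4 had them at stage 10 and at stage 18, so no value was computed there.

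The share of 25-30 nt reads at stage 10 minus stage 8 was −0.817 points by distinct positions, 8.61 with reads at 1 place, 6.99 for 24-29 nt and 8.32 without the 10 most abundant sequences. For stage 18 minus stage 10 these were −1.39, −8.80, −9.39 and −9.26, and for the vegetal minus the animal pole 1.97, 2.88, 0.453 and 2.78. Z-scores of the 10 nt overlap, weighted by reads, were 27.9, 19.8, 21.9, 13.9 and 22.9 at stages 8, 10 and 18 and in the animal and vegetal pole. In 21-23 nt reads they were 2.52, −0.227, 1.40 and 2.70 in the first 4 of these, and with reads at 1 place 11.6 at stage 8, 8.12 at stage 10 and 11.9 in the animal pole.

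In the same order of libraries, loci numbered 328, 412, 390, 341 and 327 at 200 RPM, 223, 151, 206, 214 and 257 with reads at 1 place, and 30191, 26016, 31285, 32241 and 34893 at full counts. The share of stage 8 loci found at stage 18 was 79.7% and 85.9% at merge distances of 50 and 1000 nt, 91.5% at 200 RPM and 91.0% at full counts. For stage 10 it was 77.9% and 89.7% at those distances, 59.6% with reads at 1 place and 78.9% at full counts. The share of animal pole loci found in the vegetal pole was 83.6% at 200 RPM, 95.8% with reads at 1 place and 93.5% at full counts. Loci higher in the animal pole numbered 10 with median-of-ratios scaling, 13 when scaled to all reads and 6 with reads at 1 place; higher in the vegetal pole, 12 with median-of-ratios scaling and 8 with no minimum. At least 4-fold with no minimum, 6 loci were lower at stage 10 than 8 and 6 higher at stage 18 than 10. At least 2-fold, 9 were higher and 16 lower at stage 10 than 8, 2 higher and 15 lower at stage 18 than 10, and 9 lower at stage 18 than 8.

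With a minimum of 10 reads, mRNA units at least 4-fold higher and lower numbered 1137 and 1227 (stage 10 against 8), 4749 and 5990 (18 against 10) and 4891 and 6919 (18 against 8). Fewer reads per unit widen counting error. Units lower at stage 18 numbered 2164 against stage 10 and 2538 against stage 8 with trimmed-mean scaling, and 2050 and 2423 with median-of-ratios scaling. On distinct alignments in the same units, 54 were lower at stage 10 than 8, 2105 lower at stage 18 than 10 and 2558 lower at stage 18 than 8. With the minimum also set to 10 distinct alignments, 48 were lower at stage 10 than 8 and 2590 lower at stage 18 than 8, and by all reads 139 of the 219 units lower at stage 10 than 8 had an interval that left out no difference.

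For peaks of 20-24 nt reads, scaled to all reads, 6 were higher and 167 lower at stage 10 than 8, 161 higher and 8 lower at stage 18 than 10, and 70 higher and 14 lower in the animal than the vegetal pole. With median-of-ratios scaling 15 were lower at stage 10 than 8, and 35 higher and 43 lower at stage 18 than 10. With a minimum of 20 reads the higher and lower counts were 298 and 461, 537 and 279, 294 and 189 (18 against 8) and 550 and 243 (poles). Among peaks with at least 80% of reads at 20-24 nt (208, 207, 220 and 199 peaks compared) they were 10 and 32, 45 and 8, 17 and 6, and 17 and 12. Shares of 25-30 nt reads in introns were 4.33% to 4.54% by distinct sequences, 1.80% to 2.04% with reads at 1 place and 5.35% to 5.63% at full counts.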

Other observations

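The tests of purines in distinct sequences, of small RNAs further along the same strand and of mRNA positions in units with few reads were chosen only after the result was seen, as were the counts below on shared sequences, loci outside the range of the poles and head-to-tail distances.

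Few small RNA sequences were common to all libraries, but these held most reads. Of 1026229 distinct sequences, 61192 occurred in all 5 libraries and held 83.6% to 88.1% of the reads of each, while 69.9% occurred in a single library. Among mRNA units, 1632 of 18082 were at least 4-fold higher at stage 18 than at stage 10 and within 2-fold between stages 8 and 10, and 4308 were within 2-fold in all 3 comparisons.

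The 25-30 nt reads showed no peak of reads starting right after another on the same strand. Among reads aligned to 1 place, distances of 0 to 50 nt between the end of a read and the start of the next were counted. The Z-score of 0 nt was 0.388 at stage 8, 0.111 at stage 10, 0.699 at stage 18, 0.267 in the animal pole and 0.0411 in the vegetal pole. In that order pairs were most frequent at 13, 8, 6, 6 and 6 nt, with 1318, 537, 981, 970 and 1596 pairs. They numbered 1169, 436, 880, 825 and 1366 at 0 nt and 1006, 359, 708, 724 and 1181 at 50 nt. A broad excess thus lay at short distances past 0 nt, and its source was not tested. Since the counts fall with distance, the Z-score of 0 nt does not decide whether precursors were processed stepwise.

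The stage 10 whole-embryo library stood apart from the libraries of its own poles. Across 21147 sequences the poles correlated with each other at 0.848, and with the whole embryo at 0.657 (animal) and 0.712 (vegetal). Of 1200 loci with at least 500 reads in the stage 10 whole embryo or a pole, 61.4% lay outside the range of both poles beyond counting error in that whole-embryo library. The share was 38.3% in the stage 8 and 52.0% in the stage 18 library, which took no part in choosing the loci. Loci chosen on the poles alone numbered 839. The stage 10 whole-embryo library also had the most 25-30 nt reads (6026281), which narrows its intervals. These shares therefore do not rank the libraries. Counting error in reads is argued against by sequences with many reads. Noise from few molecules read many times stays open, since a minimum of reads does not remove it. The stage 10 whole-embryo library held 33.3 reads per distinct sequence, against 11.2 to 17.1 in the others. The gap between the correlation of the poles and the mean of theirs with the whole embryo was 0.168 among sequences with at least 1000 reads. A shift in read length alone is argued against too, since that gap was 0.117 with sequences joined by their first 20 bases. Length and end bases accounted for 15.2% of the variance of the ratio, which leaves a ligation preference open. A difference between collections of embryos, or tissue outside the poles, may also be the source and was not tested. The stage 10 whole-embryo library correlated at 0.781 with stage 8 and 0.783 with stage 18, which correlated with each other at 0.874. With those stages the vegetal pole correlated at 0.855 and 0.845 and the animal pole at 0.792 and 0.764. Whole-embryo contrasts of stage 10 with stages 8 and 18 rest on this 1 library, so a stage difference and a library difference cannot be told apart.

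Purines made up 66.2% to 68.7% of the bases of 25-30 nt reads. Distinct sequences counted once held 62.3% to 65.6% purines, less than reads in every library, so abundant sequences may account for part of this. Such values argue against a few abundant sequences as the whole source. Variants of 1 RNA in length count as distinct, so its weight is not fully removed. Reads on the minor strand of loci read mainly from a single strand held 64.1% purines, as a preference for purine-rich RNA in library preparation would predict, which leaves it as a candidate explanation. No biological explanation was tested.

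The mRNA reads lay in stacks at single positions. Stack heights at positions read in both libraries had a median correlation of 0.295 between stages 8 and 10 over 628 units, between the values that random amplification and fixed positions were set to predict, so random amplification could not be excluded. Of the positions read at stage 8, 52.2% were read at stage 10, 1.18 times the 44.4% of positions 1 to 5 nt away, but the ratio was limited to 2.25 in units so densely read and decides nothing. In 6080 units of 50 to 200 reads, where it was limited to 7.88, the ratio was 1.41 (17.9% against 12.7%), between the bounds set to decide, so preferred fragment ends stay open too. No biological explanation was tested.

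A hypothesis was that peaks of 20-24 nt reads at 1 place are arms of hairpin precursors, as microRNAs are. Of 113 such peaks with at least 200 reads over the 5 libraries and at least 80% of reads at 20-24 nt, 30 (26.5%, interval 18.7 to 35.7) had a 20-24 nt partner 25 to 80 nt away on the same strand and 4 (3.54%) on the opposite strand, a ratio of 7.50. However 22 peaks (19.5%, 12.6 to 28.0) had a same-strand partner 225 to 280 nt away, 0.733 of the number nearby. Neighbouring small RNAs of a locus read from a single strand may therefore give most same-strand partners, and the positions did not tell hairpin arms apart from them.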
